A study of Mus musculus with 2 samples.

How the data were processed

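H3K4me3 ChIP-seq of unstimulated C57BL/6J bone marrow-derived macrophages was analysed from the peak lists of 2 biological replicates and from 2 lists of the whole series. Per the labels, each library began with 10 ng of DNA, the size range was 350 to 480 with no unit given, the assembly was mm10 and the replicates were separate cell preparations under the same donor entry. The labels leave open whether these came from separate animals, so differences between the replicates include technical spread. The aligner, the peak caller, their versions and their thresholds are not given in the sources used here.

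Per the provenance texts deposited with the lists, the authors made a pseudoreplicated peak list from the alignments of each replicate, a pseudoreplicated list from the alignments of both replicates together, called pooled here, and a replicated list from both. Peaks were thus called per replicate and also on pooled alignments, per the same texts. Each peak in the deposited lists carries a fold (a ratio) and −log10 p and −log10 q values, in the narrowPeak layout that the provenance texts name. The fold is the authors' own value for that peak, and what it is relative to is not stated in the lists. It was used within each list to describe, rank and filter peaks, to group genes by rank for resampling and matching, and for ratios between peaks of the same list. Ranks within each list were also compared between the replicates. No read counts or signal values were used, so depth is unknown and no precision from depth can be given. Wilson intervals on shares of peaks (95%) treat peaks as independent and cover counting error only.

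Coordinates were compared with the GRCm38.p6 assembly, which is mm10, and 0 peak ends lay beyond a chromosome's length. Genes and starts came from GENCODE release M21 on 21 chromosomes (19 autosomes, X and Y). A promoter was the window of 1000 bp on either side of a transcript start. Each peak was placed at a promoter of any gene, in an exon, in an intron or between genes, in this order. A protein-coding gene was called marked when a peak of each replicate's own list overlapped any of its windows by at least 1 bp. Its domain was formed by joining peaks within 1000 bp of each other, and the widest joined domain touching a window was measured in each replicate and averaged. At 105 of the 10869 marked genes, 0.966%, the widest domains of the 2 replicates did not overlap. Tcf4 and Gata3 are among these. The CpG observed/expected ratio was computed over the 1000 bp on either side of the 5′ end of each gene.

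Peaks of the replicates counted as shared with an overlap of at least 1 bp, and bedtools 2.31.1 placed each list at random 100 times within chromosomes for a chance level. Gene lists were fixed before the data were examined, as were the tests, the alternatives listed below and the rule for named genes. Of 481 symbols in 24 lists, 478 matched a protein-coding gene, 2 of them through a synonym. Mx2 and Clec7a are annotated as polymorphic pseudogenes and Ahsp had no match. The share of marked members was compared with all other protein-coding genes by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 24 lists. Domain widths were compared by a two-sided permutation test of the difference in medians with 100000 resamples, adjusted over the 11 lists with at least 10 marked members. The threshold was an adjusted p of 0.05. Genes are the units of these tests, so they compare lists within these libraries and say nothing of other cultures. With 2 libraries in 1 group there is no comparison between conditions. The exact p for the location of unshared peaks of replicate 1 was below the smallest number the software holds, and the odds ratio with a Wald interval is given in its place.

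The text names, from each list, the 3 marked genes with the widest domains and, in alphabetical order, up to 3 unmarked genes and up to 3 with a peak in 1 replicate. It also names the 10 widest domains, the 5 highest folds by mean rank, the 3 highest folds among genes marked in each replicate alone, and the 5 replicated peaks of highest fold over 5000 bp from any start. Not every one of the 156 genes chosen by this rule is described, and some are not reported here. Csf1r, H2-Ab1, H2-Eb1 and H2-DMb1 were named in addition, after their values were seen, as were the genes of the closing section.

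The overlap routine was tested on simulated data: a shifted copy holding 75% of the 20031 peaks of replicate 1 gave a shared share of 76.0%, and 500 of 500 peaks had the same answer as a direct search. Simulated lists of 20 genes marked at 90% against a base of 50% were called in 99.0% of 1000 runs, and lists marked at the base rate in 3.9%. Simulated lists of 20 domain widths raised 1.5 times were called in 74.0% of 200 runs, raised 2 times in 97.0%, and unchanged in 5.0%. All simulated lists were called at an unadjusted p under 0.05. The simulated widths were those of all joined domains of replicate 1, not of promoter domains averaged over the replicates. These rates are therefore not those of the adjusted tests.

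Alternatives were promoter windows of 500 and 2500 bp, 1 start per gene, starts of protein-coding genes only, peaks with −log10 q of at least 5, the 15000 peaks of highest −log10 p, overlap of 50% of either or of both peaks, no joining and joining over 3000 bp, the authors' pooled and replicated lists, each replicate alone, backgrounds matched on CpG tertiles, and the omission of genes whose window holds another gene's start. Resampling of widths within tertiles of the number of starts and of the fold was added after the data were seen. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.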

Results

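Trimethylation of histone H3 at lysine 4 (H3K4me3), a mark of active and poised promoters, was mapped by chromatin immunoprecipitation and sequencing in bone marrow-derived macrophages of C57BL/6J mice that had received no stimulus. These are primary cells grown out of bone marrow progenitors. There was 1 group with 2 biological replicates, which the labels give as separate cell preparations of the same mouse donor entry, each starting from 10 ng of DNA. No other condition was measured, so the comparisons are between the replicates, between parts of the genome and between groups of genes, and every p-value compares lists of genes or peaks within these 2 libraries. Read counts are not part of the peak lists and sequencing depth is therefore unknown.

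Replicate 1 had 20031 peaks covering 25.5 Mb and replicate 2 had 16376 peaks covering 17.8 Mb, a mean of 18203.5 ± 2584 peaks (SD, n = 2). Nearly all of the smaller list lay within the larger one. Of the peaks of replicate 2, 99.9% overlapped a peak of replicate 1 by at least 1 bp and 10 did not, whereas 73.9% of the peaks of replicate 1 overlapped a peak of replicate 2 (95% Wilson interval 73.3 to 74.5%) and 5235 did not. Random placement of the other list on the same chromosomes gave 1.60% for replicate 1 and 1.95% for replicate 2, as means of 100 placements. With the threshold set to the 15000 peaks of highest −log10 p in each list, 90.9% of the peaks of replicate 1 were shared.

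Enrichment ranked the shared peaks in nearly the same order in both libraries. Across the 13291 peaks matched 1 to 1, Spearman's rho was 0.977 for the fold enrichment that the authors' peak caller gave and 0.927 for the width. These are correlations across peaks, which are not independent replicates. Of the matched peaks, 98.3% were wider in replicate 1, with a median ratio of 1.25. Sharing followed the authors' fold in replicate 1: 4.79% of peaks in the lowest quintile of fold were shared, 64.7% in the next quintile, 99.8% in the middle quintile and 100% in both upper quintiles.

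Promoters held most of the peaks. Within 1 kb of an annotated start of any gene lay 81.4% of the peaks of replicate 1 and 90.2% of those of replicate 2, a mean of 85.8 ± 6.19% (SD, n = 2), in 5.88% of the genome. Introns held 5.39 ± 2.56% of peaks against 37.3% of the genome, intergenic sequence 6.94 ± 2.94% against 53.7%, and exons 1.88 ± 0.692% against 3.09% (SD, n = 2 for each). A peak counted at a promoter with any overlap, whereas genome shares count base pairs, so the shares of peaks and of the genome are not like measures. The promoter share was 84.0% in the authors' pooled list and 87.1% in their replicated list. When only the 5′ end of each gene counted as a start, the mean promoter share was 75.9%.

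**Figure D1:**
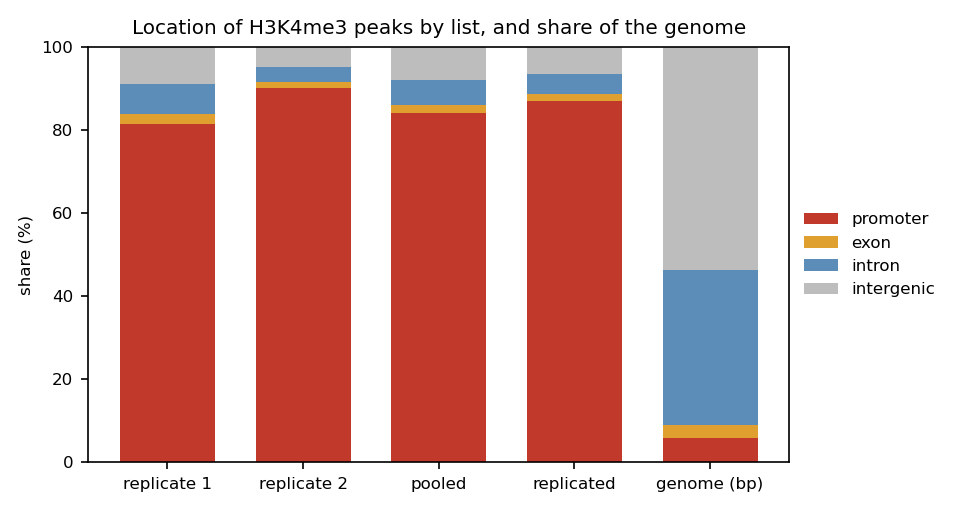
Stacked bars of the share of peaks (%) at promoters, in exons, in introns and in intergenic sequence for each of the 4 peak lists, with the share of the genome in base pairs in the last bar. The promoter class takes 81.4% to 90.2% of the peaks of the lists and 5.88% of the genome.

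Of 21938 protein-coding genes, 10869 (49.5%) carried a promoter peak in both replicates, 878 in replicate 1 only, 1 in replicate 2 only and 10190 in neither. Genes marked in both replicates had a median promoter domain of 1946.5 bp, with an interquartile range of 1430.5 to 2546.5 bp. Marking followed the CpG content of the promoter sequence: 12.1% of genes in the lowest tertile of the CpG observed/expected ratio were marked in both replicates, 56.0% in the middle tertile and 80.5% in the highest tertile. Of the marked genes, 25.1% shared the promoter window with the start of another protein-coding gene, so that a peak there cannot be assigned to 1 of the genes.

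Genes of the macrophage itself carried the mark almost throughout. In the macrophage lineage list 28 of 30 members had a promoter peak in both replicates, including Csf1r, which encodes the receptor for the growth factor that maintains macrophages, and the transcription factor gene Maf. Cx3cr1, a chemokine receptor gene, had no peak within 1 kb of an annotated start, the nearest peak of replicate 1 lying 40341 bp away, and Axl, a receptor of apoptotic-cell clearance, had a peak in replicate 1 only. All 25 lysosome and phagocytosis genes were marked, among them Psap, Ctsb and Ctsd, and so were 24 of 25 genes of lipid and cholesterol metabolism, with Scd2 and Hmgcs1 among the marked members and Fabp4 marked in replicate 1 only. By Fisher's exact test against all other protein-coding genes, the adjusted p was 2.24e-06 for the macrophage lineage, 2.81e-07 for the lysosome and 3.15e-06 for lipid metabolism. Of the other genes, 49.5% were marked in each of these comparisons. Of genes matched on CpG tertiles the marked share was 34.6%, 62.1% and 65.8%, respectively. The excess was thus larger for the macrophage lineage and smaller for the other lists, and each list still passed (adjusted permutation p = 8.0e-05, 8.0e-05 and 0.00166).

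Signalling and sensing genes were marked as a group. All 30 genes of NF-κB, IRF and STAT signalling carried peaks in both replicates (adjusted p = 1.66e-08, Fisher's exact test), among them Irf5, Rel and the adaptor gene Myd88, whose window also holds the start of Acaa1a. Of 20 pattern-recognition receptors 16 were marked (adjusted p = 0.0101, Fisher's exact test), including the inflammasome sensor gene Nlrp3, the DNA sensor gene Cgas and Tlr8. Tlr9 had a peak in replicate 1 only, and Tlr11, Tlr12 and Clec4n had none in either replicate. Of 20 antigen presentation genes 17 were marked (adjusted p = 0.00233, Fisher's exact test), with B2m and H2-D1 of class I among them. On the class II side H2-Ab1, H2-Eb1, H2-DMb1 and H2-DMa were marked in both replicates, the last with the start of Brd2 in its window, while Cd74, the invariant chain gene, and Ciita, the class II transactivator gene, had peaks in replicate 1 only, with folds of 3.01 and 5.23, and H2-Aa had none. The antigen presentation list no longer passed the threshold with 1 start per gene (adjusted p = 0.0528, Fisher's exact test). Of genes matched on CpG tertiles 63.9% were marked for signalling, 28.7% for pattern-recognition receptors and 42.1% for antigen presentation. Each list passed against this background (adjusted permutation p = 8.0e-05, 8.0e-05 and 1.37e-04, respectively).

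Lists of genes that stimulation switches on were each compared with all other genes and not with one another, and no stimulus was given. Of 20 immediate early genes 19 were marked (adjusted p = 4.79e-05, Fisher's exact test), including Atf3, Zfp36 and Klf6, and Egr3 had a peak in replicate 1 only. Against a background matched on CpG tertiles their excess was smaller, with 95% of members marked against 69.7% of matched genes (adjusted permutation p = 0.0134). Of 24 interferon-stimulated genes 21 were marked (adjusted p = 3.30e-04, Fisher's exact test), including Rsad2, Mx1 and Usp18. The chemokine gene Cxcl10 and Ifi44 had peaks in replicate 1 only and Cxcl9 had none. With CpG tertiles matched, 87.5% of interferon-stimulated genes were marked against 32.5% of matched genes (adjusted permutation p = 8.0e-05). The primary inflammatory response list, with 12 of 20 marked, did not pass the test (adjusted p = 0.433, Fisher's exact test). With CpG tertiles matched, 60% of its members were marked against 39.7% of matched genes, which did not pass either (adjusted permutation p = 0.0952). The feedback inhibitor genes Nfkbia and Tnfaip3 and the adhesion molecule gene Icam1 were marked. Cxcl1, Cxcl2 and Ptgs2, which encodes an inducible cyclooxygenase, had peaks in replicate 1 only, and Il1a, Ccl5 and Cxcl3 had none.

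Of 20 secondary inflammatory response genes 5 were marked, which did not pass the test (adjusted p = 0.0524, Fisher's exact test). Il10, Edn1 and Ebi3 had peaks in both replicates, Il6, Il12a and Il27 in replicate 1 only, with folds of 4.67, 9.53 and 7.66, and the cytokine genes Csf2, Csf3 and Ifnb1 had none. With a window of 2500 bp the list was marked less often than other genes (adjusted p = 0.0324, Fisher's exact test), likewise with 1 start per gene (adjusted p = 0.0328, Fisher's exact test). Against a background matched on CpG tertiles the direction turned, with 25% of members marked against 22.1% of matched genes (adjusted permutation p = 0.923). Of 19 alternative activation genes 8 were marked (adjusted p = 0.676, Fisher's exact test). The receptor gene Il4ra, its signal transducer Stat6 and the mannose receptor gene Mrc1 were marked, Arg1, Il1rn and Socs2 had peaks in replicate 1 only, and the chemokine genes Ccl17, Ccl22 and Ccl24 had none. The direction of this list turned with the CpG-matched background (adjusted permutation p = 0.516) and without replicate 2 (adjusted p = 0.820, Fisher's exact test).

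**Figure D2:**
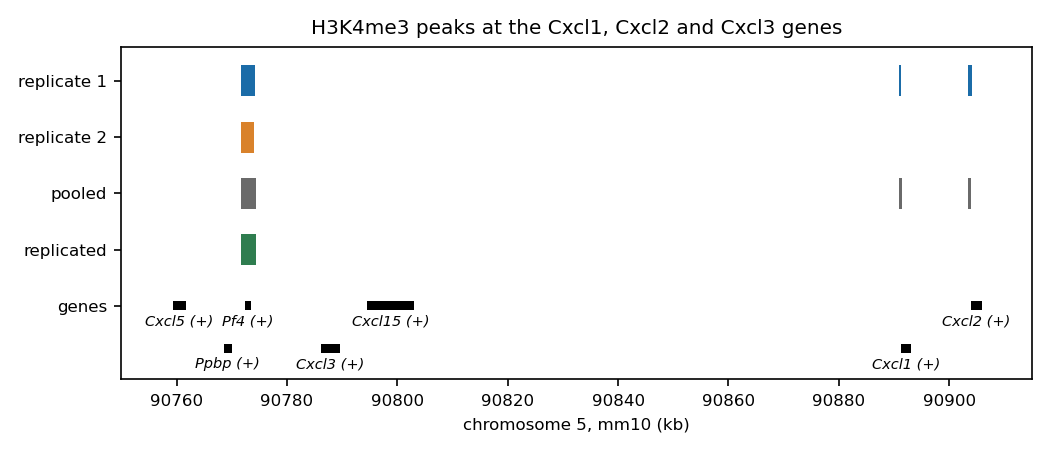
Map of the chemokine gene cluster on chromosome 5 (mm10, kb), with the peaks of the 4 lists as blocks and protein-coding genes as black bars with their strand. Pf4 lies under a peak in all 4 lists, Cxcl1 and Cxcl2 have short peaks of 443 and 588 bp in replicate 1, and peaks there in the pooled list, and Cxcl3 has none.

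Housekeeping genes were marked in 20 of 20 cases (adjusted p = 3.15e-06, Fisher's exact test) and histone methylation enzymes in 23 of 25 (adjusted p = 2.66e-05, Fisher's exact test), with Setd1b, Kmt2d and Kmt2a, which encode methyltransferases of H3 lysine 4, having the widest domains of that list when peaks were joined. With no joining these measured 3245, 2603 and 1897 bp. Kdm5b, which encodes a demethylase of the same residue, had a peak in replicate 1 only. Kdm6b, a demethylase gene of H3 lysine 27, had no peak within 1 kb of its annotated start but lay 1404 bp from a peak of replicate 1, and was marked in both replicates with a window of 2500 bp. Against backgrounds matched on CpG tertiles the excess of both lists was smaller. Of matched genes 68.8% were marked for housekeeping (adjusted permutation p = 4.27e-04) and 73.0% for histone methylation enzymes (adjusted permutation p = 0.0328).

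Genes of other cell types were mostly unmarked. Of the 25 genes restricted to other organs none had a peak in both replicates (adjusted p = 4.82e-07, Fisher's exact test): the albumin gene Alb, Afp and the muscle gene Actn2 had none, and the synaptic gene Syp had a peak in replicate 1 only. Of 25 developmental regulators 1 was marked (adjusted p = 5.36e-06, Fisher's exact test), and Bmp4, Cdx2 and Dlx5 were not. Of 15 fibroblast and stroma genes 1 was marked, the transcription factor gene Runx2 (adjusted p = 0.00181, Fisher's exact test), while the collagen genes Col1a1, Col1a2 and Col3a1 had no peak.

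Among lists of other blood cells, 4 were marked less often than other genes. The B cell list had 1 marked gene of 15 (adjusted p = 0.00181, Fisher's exact test), Vpreb1, whose window holds the start of Top3b, and Cd22 and Blk had no peak. The neutrophil and granule protein list had 1 of 16, the transcription factor gene Gfi1 (adjusted p = 0.00114, Fisher's exact test), with Camp, Ctsg and Cebpe unmarked. The mast cell and basophil list had 1 of 12, the histidine decarboxylase gene Hdc (adjusted p = 0.0101, Fisher's exact test). The dendritic cell list had 2 of 14, Tcf4 and Batf3 (adjusted p = 0.0183, Fisher's exact test). Against a background matched on CpG tertiles the B cell, neutrophil and mast cell lists no longer passed the threshold, with adjusted permutation p of 0.0768, 0.164 and 0.258. The dendritic cell list did not pass it with the authors' pooled list (adjusted p = 0.325, Fisher's exact test), without replicate 2 (0.233) or without genes whose window holds another gene's start (0.0675).

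The remaining lists did not pass the test. Of 17 T and NK cell genes 4 were marked, with Cd28 and Lck among them (adjusted p = 0.0589, Fisher's exact test), and of 12 endothelial genes 2 were marked, Kdr and Pecam1, the latter with the start of Milr1 in its window (adjusted p = 0.0515, Fisher's exact test). With a window of 2500 bp both lists were marked less often than other genes, with adjusted p of 0.0358 and 0.0289 by Fisher's exact test. The T and NK cell list also passed with 1 start per gene (adjusted p = 0.00151, Fisher's exact test) and the endothelial list with the authors' replicated list (adjusted p = 0.0261, Fisher's exact test). Against the CpG-matched background neither list passed, with 23.5% of T and NK cell genes against 31.9% of matched genes (adjusted permutation p = 0.573) and 16.7% of endothelial genes against 39.8% (adjusted permutation p = 0.149). Of 14 erythroid and megakaryocyte genes 6 were marked (adjusted p = 0.791, Fisher's exact test), among them Tal1, the platelet factor gene Pf4 and Epor, and the direction turned with the CpG-matched background (adjusted permutation p = 0.238). Of 15 stem and progenitor cell genes 6 were marked (adjusted p = 0.663, Fisher's exact test), among them Meis1, Lmo2 and Mllt3, and Cd34, Ctnnal1 and Esam had peaks in replicate 1 only. The direction of this list turned with the authors' replicated list, with their pooled list and without replicate 2 (adjusted p = 0.635, 0.341 and 0.233, Fisher's exact test).

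For some named genes the call depended on the start or the window. With 1 start per gene, Atf3, Cd28, Lck, Hdc and Lmo2 had no peak in either replicate, and Gfi1 and Runx2 had a peak in 1 replicate. With a window of 2500 bp, Egr3, Socs2 and Cebpe were marked in both replicates.

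**Figure D3:**
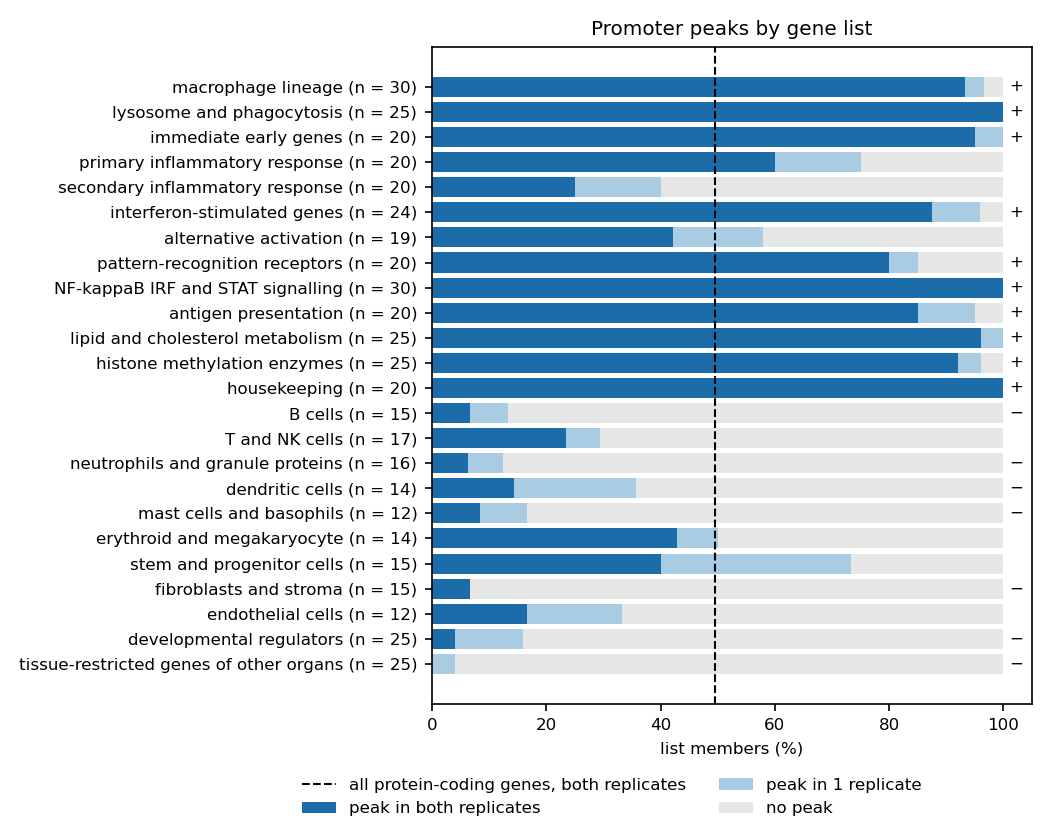
Share of the members of each of the 24 gene lists (%) with a promoter peak in both replicates (dark), in 1 replicate (light) or in neither (grey), with the dashed line at the 49.5% of all protein-coding genes marked in both. A plus sign stands beside the 10 lists marked more often and a minus sign beside the 7 lists marked less often than other genes at an adjusted p under 0.05.

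Promoter domains were wider at genes of the macrophage, the lysosome, the immediate early response and housekeeping than at other marked genes. The median width was 3171.5 bp over 28 macrophage lineage genes, 3119 bp over 25 lysosome genes, 3125.5 bp over 19 immediate early genes and 3117 bp over 20 housekeeping genes, compared with 1945.5 to 1946 bp over the remaining marked genes. In these lists 24 of 28, 21 of 25, 14 of 19 and 17 of 20 members lay above the median of the others. The adjusted p of the permutation test was 1.10e-04, 1.10e-04, 1.47e-04 and 2.20e-04, respectively. For the macrophage and lysosome lists the unadjusted value was 2.0e-05, the smallest that the resampling can give.

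Among named members of these lists, Psap, which encodes the precursor of the saposins that activate lysosomal lipid hydrolases, had a domain of 11417 ± 3376 bp, and the cathepsin genes Ctsb and Ctsd had domains of 8598 ± 1765 bp and 6678 ± 1017 bp (SD, n = 2 for each). Maf had 8432 ± 498 bp, Sirpa, which encodes an inhibitory receptor that binds CD47, 5868 ± 3042 bp and Mpeg1, a pore-forming protein gene of macrophages, 5521 ± 496 bp (SD, n = 2 for each). Atf3 had 7333.5 ± 848 bp, Zfp36, which encodes an mRNA-destabilising protein, 6365.5 ± 2101 bp and Klf6 6156.5 ± 332 bp. The housekeeping gene Actb had 6874.5 ± 849 bp (SD, n = 2). Part of this width came from joining neighbouring peaks: with no joining the widths were 3027 bp at Actb, 4233.5 bp at Atf3 and 4960 bp at Maf. With joining over 3 kb they were 11328.5 bp at Ctsd and 10630 bp at Zfp36.

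**Figure D4:**
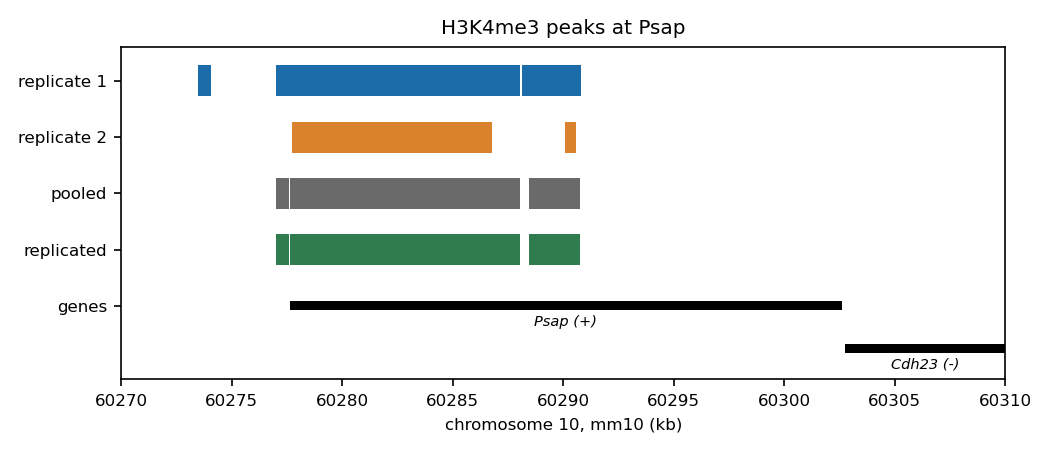
Map of the Psap gene on chromosome 10 (mm10, kb), with the peaks of the 4 lists as blocks and protein-coding genes as black bars with their strand. The main peak lies at the annotated start and extends into the gene, with a whole length of 11070 bp in replicate 1 and 9030 bp in replicate 2.

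Lipid metabolism genes also had wider domains, with a median of 2891 bp over 24 genes (adjusted permutation p = 3.52e-04). Their difference from other marked genes was 945.25 bp, and it ranged from 529.5 to 1458 bp over the alternatives (adjusted permutation p of at most 0.0210). Scd2, which encodes a stearoyl-CoA desaturase, had 6510 ± 498 bp, and Hmgcs1, a gene of cholesterol synthesis, had 3857.5 ± 356 bp (SD, n = 2 for each). The medians were 2659 bp over 12 primary inflammatory genes (adjusted permutation p = 0.0324), 2608 bp over 21 interferon-stimulated genes (adjusted permutation p = 0.0112) and 2612 bp over 23 histone methylation enzymes (adjusted permutation p = 0.00766). Nfkbia had a domain of 3783 ± 1010 bp, Rsad2 of 3501.5 ± 667 bp and Setd1b of 7726.5 ± 2661 bp (SD, n = 2 for each). With no joining Nfkbia measured 2251 bp and Setd1b 3245 bp, and with joining over 3 kb Setd1b measured 12968.5 bp. The primary inflammatory list did not pass the threshold without replicate 1 (adjusted permutation p = 0.0859) or with joining over 3 kb (0.105), the interferon-stimulated list without replicate 1 (0.0987), and the histone methylation list with no joining (0.912), or with resampling within tertiles of the fold (0.0502), a setting chosen after the data were seen.

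Pattern-recognition receptors, signalling genes and antigen presentation genes did not differ from other marked genes in this test, with medians of 1980.25 bp, 2139.75 bp and 2163 bp and adjusted permutation p of 0.898, 0.408 and 0.461. The direction for pattern-recognition receptors turned without replicate 1 (adjusted permutation p = 0.674) and with the authors' replicated list (0.423). With no joining of peaks, the antigen presentation list had wider domains than other genes (adjusted permutation p = 0.0196). Members with wide domains were Irf5 with 4529.5 ± 353 bp, B2m with 4730.5 ± 654 bp and Nlrp3 with 3431 ± 358 bp (SD, n = 2 for each). With no joining Irf5 measured 2897 bp.

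**Figure D5:**
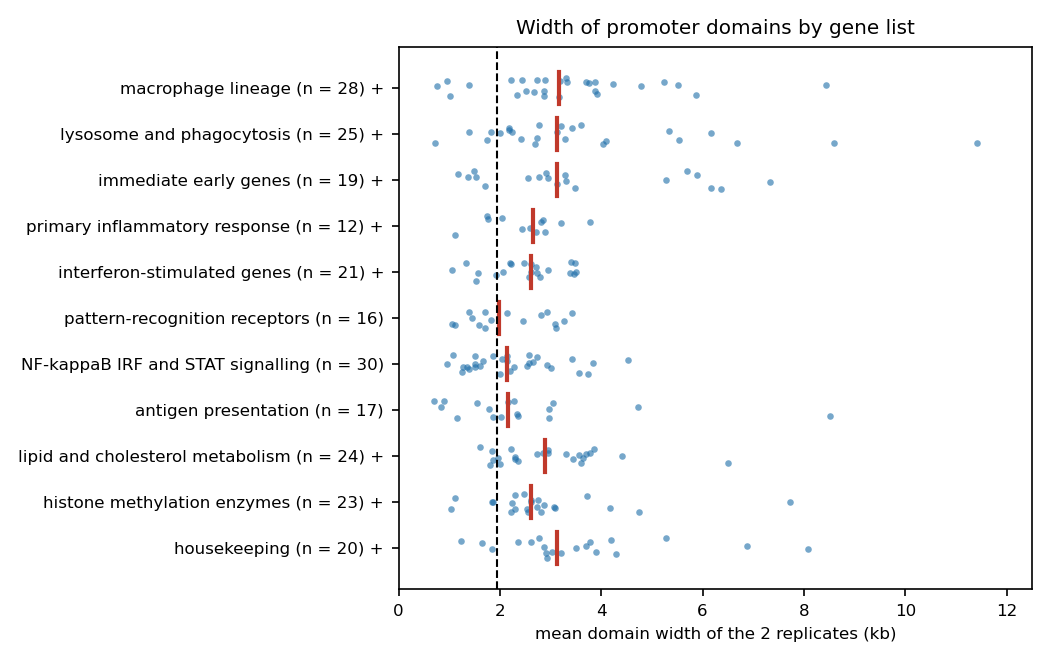
Promoter domain width in kb, as the mean of the 2 replicates, for each marked gene (points) of the 11 lists with at least 10 marked members, with the list median (red bar) and the median of 1946.5 bp over all marked genes (dashed line). A plus sign marks the 8 lists with wider domains than the other marked genes at an adjusted permutation p under 0.05.

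Among promoter domains of all marked protein-coding genes, with peaks joined within 1 kb, the widest were at Psap, on chromosome 10 from 60276980 to 60290783 in replicate 1 and from 60277739 to 60286768 in replicate 2, and at BC005537, on chromosome 13 from 24799271 to 24811240 and from 24799590 to 24809630, with 11005.5 ± 1364 bp, followed by Tnrc18 with 9886 ± 359 bp (SD, n = 2 for each). Lpxn and Zfp91 share a domain of 8741 ± 655 bp, Brd2 and H2-DMa share one of 8518 ± 836 bp, and Apobec1, a cytidine deaminase gene, had 8294.5 ± 1633 bp (SD, n = 2 for each). With no joining these widths were 5599.5 bp at Tnrc18, 3415.5 bp at Lpxn, 2075 bp at Zfp91 and 2765 bp at Brd2 and H2-DMa. The order depends on the joining: over 3 kb Setd1b, not among the widest at 1 kb, measured 12968.5 bp. The highest folds by mean rank were at M6pr, which encodes a mannose-6-phosphate receptor that sorts enzymes to lysosomes, with 69.9 in replicate 1 and 32.8 in replicate 2, at the start shared by Hadha and Hadhb, with 69.1 and 30.9, and at the start shared by Usmg5 and Pdcd11, with 67.8 and 30.9. These 5 genes had domains of 2171 to 2804 bp. Across marked genes, the rho between fold and width was 0.398 in replicate 1 and 0.479 in replicate 2.

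The 5235 peaks of replicate 1 without a partner in replicate 2 were weaker, narrower and less often at promoters than the shared ones. Their median fold was 5.23 against 30.6, their median width 479 bp against 1341 bp, and 55.1% lay at promoters against 90.7%, an odds ratio of 0.126 (95% interval 0.116 to 0.136). Of these peaks 18.97% lay in introns and 20.6% between genes. The 10 peaks found only in replicate 2 had a median fold of 2.84. Genes marked in replicate 1 only had a median fold of 5.79 there, against 38.9 at genes marked in both.

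The highest folds among genes marked in replicate 1 only belonged to Tbc1d10c, Gm17334 and Exoc3l, with 57.9, 52.1 and 48.4. Tbc1d10c has the start of Ppp1ca, and Gm17334 that of Irf1, within its window. All 3 were marked in both replicates with a window of 2500 bp. Their folds lie in the highest quintile of replicate 1 (41.7 to 69.9), where 100% of peaks overlapped a replicate 2 peak. These peaks were thus present in replicate 2 but lay outside the window of 1000 bp there. The only gene marked in replicate 2 alone was Pram1, with a fold of 3.13 and a peak of 488 bp.

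Of the authors' 18898 pooled peaks, 16890 (89.4%) were present with the same ends in their replicated list of 16957 peaks. The 2008 pooled peaks outside it had a median fold of 3.59 and a median width of 428.5 bp, 98.1% of them overlapped a peak of replicate 1 and 0% a peak of replicate 2. Peaks at Cxcl1 and Cxcl2 were among them. A further 67 replicated peaks were not in the pooled list, and 37.3% of them overlapped a peak of replicate 1 and 0% a peak of replicate 2. Of the 16890 peaks in both lists, 99.8% overlapped a peak of replicate 1 and 88.9% a peak of replicate 2. A replicated peak thus need not have a partner in each replicate's own list. Promoters held 56.8% of the pooled peaks outside the replicated list and 87.3% of those inside it.

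Peaks over 5 kb from any annotated start made up 7.98% of the replicated list, 1353 in number, with a median width of 758 bp against 1211 bp for the others. The highest fold among them, 39.1, belonged to an intergenic peak on chromosome 16 from 64872818 to 64874410, 20116 bp from the nearest start, that of Cggbp1. The next were intergenic peaks on chromosome 1 from 171037109 to 171038800 with a fold of 37.4, on chromosome 13 from 21974053 to 21975181 with 36.9, 6013 bp from a start of Pom121l2, on chromosome 14 from 118088579 to 118090609 with 36.4, and on chromosome 2 from 166786019 to 166787245 with 36.2, 5286 bp from a start of Trp53rkb.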

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

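Resampling within tertiles of the number of starts or of the fold was chosen after the data were seen. No paired analysis was possible because there is 1 group. The cause was not tested for any of the changes below unless the setting itself gives it. The share of replicate 2 peaks found in replicate 1 was 81.4% with reciprocal overlap of 50%, 99.99% with −log10 q of at least 5 and 99.6% with the 15000 top peaks. The share of replicate 1 peaks was 66.6%, 74.5% and 90.9% in these settings and 77.9% with joined peaks. The rho of fold was 0.980 with −log10 p in its place and 0.975 with reciprocal overlap. The mean promoter share fell to 75.9% with 1 start per gene and was 81.4 to 90.2% with 1 replicate left out. Leaving out 1 replicate gave 10870 to 11747 marked genes, 16 to 17 lists that differed in marking and 6 to 9 lists with wider domains. Over all settings, 220 of the 240 pairs of list and setting kept their direction and side of the threshold for marking, as did 102 of 110 for width. Directions changed only in lists that passed no threshold in either setting. In marked share minus that of other genes, stem and progenitor cells turned to 8.72 percentage points with the replicated list and 13.96 with the pooled list. With 1 replicate left out it lay between -9.56 and 19.8, and for alternative activation between -7.45 and 4.35. With CpG tertiles matched, alternative activation turned to 8.94, secondary inflammatory genes to 2.89 and erythroid genes to 16.5. The width difference of pattern-recognition receptors turned to -195 bp with the replicated list and lay between -121 and 140 bp with 1 replicate left out. Of 156 named genes, 31 changed the number of replicates with a peak in at least 1 setting, and 25 of 68 named widths moved by over 1.5 times with no joining or joining over 3000 bp. Depth is unknown, so a promoter without a peak may lie below what these libraries could detect.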

Other observations

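The 3 lists in the comparison of lost peaks and the tests of the chromosome Y and X partner folds, of the distance to replicate 2 peaks, of the number of starts and of peak strength were chosen only after the results were seen. The CpG setting was among the alternatives fixed beforehand, but its use as a test of that explanation was chosen after its result was seen. Gene families were grouped by symbol, also after the data were seen, and some of their members are also in the lists. Chemosensory receptor genes were almost devoid of the mark: 2 of 1135 olfactory receptor genes and 1 of 329 vomeronasal receptor genes were marked in both replicates. Olfr56 shares its window with the start of Ifi47 and Vmn1r4 with that of Nt5c3, while Olfr111, with a domain of 2037 ± 850 bp (SD, n = 2), has no other coding start in its window. None of 42 beta-defensin genes and none of 14 interferon alpha genes had a peak in either replicate, and 1 of 53 keratin genes, Krt10, was marked. Of NADH dehydrogenase subunits 36 of 37 were marked, of proteasome subunits 37 of 39 and of ribosomal protein genes 81 of 91, at median widths of 1873, 1985.5 and 2233 bp. Among the 10 unmarked ribosomal protein genes, 6 carry pseudogene symbols, and with kinases and other genes of similar symbol included the share was 88.1%, against 89.0% without them. No family was tested against other genes. Vacuolar ATPase subunits, which acidify lysosomes, were marked in 15 of 23 cases with a median width of 2767 bp, led by Atp6v1a with 6162.5 ± 715 bp and Atp6v0c with 5206.5 ± 1387 bp, and cathepsins in 10 of 23 with 2986 bp (SD, n = 2 for each gene). The window of Atp6v1a also holds the start of Naa50, so its domain cannot be assigned to Atp6v1a alone. Atp6v1a, Atp6v0d1, Ctsa, Ctsb, Ctsd, Ctsl, Ctss and Ctsz are also members of the lysosome list, where all were marked. The widths of the vacuolar ATPase and cathepsin families are thus not separate from those of that list.

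Of 5134 long intergenic noncoding RNA genes over 5 kb from any protein-coding start, 194 (3.78%) were marked in both replicates. Neat1, the RNA scaffold of paraspeckles, had peaks of 7563 and 5873 bp in replicates 1 and 2, and Lncpint peaks of 2680 and 2266 bp. Protein-coding genes on chromosome X were marked in 34.1% of cases (323 of 948) against 50.7% on the autosomes. Among Hox genes 5 of 39 were marked, among them Hoxb4 with a domain of 2416 ± 194 bp (SD, n = 2).

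Xist, the RNA gene that silences an X chromosome in female cells, carried a peak in both replicates, with folds of 31.0 and 17.5, while 4 promoters on chromosome Y had peaks in replicate 1 (Kdm5d, Eif2s3y, Uty and Ddx3y, folds 7.85 to 11.8) and 1 of them, Ddx3y, in replicate 2 (3.26). The authors' pooled and replicated lists each held 4 peaks on chromosome Y. The labels record no sex. Reads of copies with identical 36-base words placed on chromosome Y are argued against, since 0.164% of such words of these peaks occur elsewhere on the assembled chromosomes. Only exact matches were counted, so copies that differ within most words or are missing from the assembly are not covered. In replicate 1 the fold at the chromosome Y promoters was 0.188 of that at their X-linked partners (median of 4 pairs, from 0.147 to 0.364), and it was 0.373 at the 1 pair with a chromosome Y peak in replicate 2. Male and female cells in 1 culture and mixing between libraries cannot be told apart by these folds. Both could give low folds on chromosome Y, but what the fold is relative to is not stated. There was also no library of male cells alone to compare with, and no biological explanation was tested.

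Of the 34 primary inflammatory, secondary inflammatory and alternative activation genes with a promoter peak in replicate 1, 9 (26.5%) had none in replicate 2. Of all protein-coding genes with a promoter peak in replicate 1 the share was 7.47%. The 9 genes were Arg1, Cxcl1, Cxcl2, Il12a, Il1rn, Il27, Il6, Ptgs2 and Socs2. Peaks of replicate 2 that end just outside the window are argued against, since the nearest replicate 2 peak lay 8550 bp or more from the replicate 1 promoter peak at these 9 genes, whereas it lay within 2500 bp at 5.35% of the 878 genes marked in replicate 1 only. At Socs2 a replicate 2 peak lay 1891 bp from another start but 21440 bp from the replicate 1 peak. Lower enrichment in replicate 2 that acts on all promoters alike is consistent with the data: genes matched on deciles of the replicate 1 fold would lose 23.5%, a difference of 2.96 percentage points (permutation p = 0.771). The fold-matched test rests on 34 genes, and a small difference in activation between the cultures stays open and untested.

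Lysosome genes had wider promoter domains, by 1173.5 bp in the median. CpG content, several annotated starts per gene and the strength of the peaks are argued against as the whole cause, since the adjusted permutation p was 7.33e-05, 1.32e-04 and 1.47e-04 when members were redrawn within tertiles of each measure. Tertiles are coarse, so a part of the difference may still come from them. Housekeeping genes had a median of 3117 bp beside 3119 bp for lysosome genes, so wide domains were not confined to genes of macrophage function. No biological explanation was tested, since the design has 1 group.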
